A study of Schizosaccharomyces pombe with 4 samples.

How the data were processed

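RNA bound to Mmi1 was measured in wild-type fission yeast of strain SPV8. Per the labels' protocols, 200 ml cultures in rich medium with adenine were grown at 30 °C and 220 rpm to an OD595 of 1.2, RNA-protein complexes were recovered with anti-Mmi1 or an irrelevant antibody, and RNA was extracted with phenol and chloroform. The sheared RNA was ligated to a 5' adapter, reverse-transcribed with random hexamers, amplified by PCR and sequenced on a HiSeq2000, also per the labels. The 4 libraries fall into 2 groups of 2, control IP and Mmi1 IP, taken from the labels. Replicate numbers follow the order of the deposited records and were not used to pair samples. The deposited file names carry BC for control IP 1 and Mmi1 IP 1 (reads of 47 bases). They carry LT for control IP 2 and Mmi1 IP 2 (reads of up to 53 bases). The sample titles, in contrast, carry BC for all 4 libraries, so the split rests on file names and read length. These 2 series, which coincide with the replicate numbers, were treated as a technical batch. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

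The deposited values are read counts per distinct sequence. For each library the deposited files hold 1 table of distinct mapped sequences with position, strand, gene and read count, and 1 table of all distinct sequences with their read count. The aligner, its settings, the genome build and any filters are not given in the sources used here. Every deposited mapped sequence without an undetermined base matched assembly ASM294v3 exactly (100%) on chromosomes I to III at the deposited position, so this assembly and its RefSeq annotation were used for all coordinates, which are 1-based. Mapped reads made up 68.7% of all reads in control IP 1, 63.9% in Mmi1 IP 1, 85.2% in control IP 2 and 86.6% in Mmi1 IP 2. The 95% Wilson intervals of these shares and of the rRNA shares (scipy 1.17.1) reached at most 0.0223 percentage points to each side. The libraries hold no molecular identifiers, and each distinct sequence that was not rRNA had a mean of 7.96, 20.7, 9.93 and 19.5 reads, in the same order. Intervals and floors therefore cover the counting error of reads only. They take copies of a fragment as independent reads, so they are too narrow where reads are copies.

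Reads were counted again from the positions (Python 3.11.15, numpy 2.4.6, pandas 2.3.3). A read was assigned to the gene on its strand that any of its bases touched, and 99.4%, 99.3%, 99.4% and 99.1% of reads over mRNA genes lay on the sense strand. Reads touching more than 1 gene of that strand (0.833%, 0.950%, 1.00% and 0.976% of reads other than rRNA) and reads in no gene (1.11%, 1.52%, 1.24% and 1.79%) were left out of the gene counts. Of 12644 annotated genes, 5574 passed edgeR's filterByExpr with a minimum count of 10 and were tested. CPM is the number of reads per 1000000 gene reads after TMM scaling, with factors of 0.72, 1.01, 1.16 and 1.19, and log-CPM uses a prior count of 2. A floor is the CPM of 3 reads. A ratio against 1 control read carries an exact counting interval in place of a fitted fold. Reads whose first 40 bases occur elsewhere in the genome were called repeated (5.50%, 5.47%, 5.49% and 5.19%).

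The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) of Mmi1 IP against control IP over all 4 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. The SE of a log2 fold change is its size divided by the square root of the F statistic. The biological coefficient of variation was 0.574. Gene lists were tested with fry and camera in limma 3.58.1, camera with a preset correlation of 0.01 and also with the correlation estimated from the data, over 15 lists written down beforehand. The list members nam2, nam7, prt1 and caf40 matched no annotated gene and nam4 matched 2, so they were left out. Transcripts were split at 3 or more sense UNAAAC hexamers, and each of the possible hexamers was regressed on with log2 transcript length as a covariate. Read density was taken within 100 nucleotides of a hexamer, in genes with at least 10 reads. Windows of 500 bases were tested on each strand. Shares of RNA classes were compared by exact permutation. Introns (4442) were scored by reads across the exon-intron border and by reads among the unmapped sequences that join 2 exons with at least 6 bases on each side. Plots were drawn with matplotlib 3.10.9.

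The 2 libraries of a group were checked for being the same library. The chi-square of their counts over genes was 676 per degree of freedom for the control IPs and 205 for the Mmi1 IPs, so each was kept as a sample.

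The genes named were fixed by a rule before the data were examined. Since fewer than 10 genes rose, the rule took the 15 genes with the smallest p and a positive fold. It also took every member of the lists of known meiotic targets, known non-coding RNAs and the genes these control, the 5 non-coding genes with the smallest p, up to 4 genes with the smallest p from each other list, and the 5 windows outside annotated genes with the smallest p. One gene that this rule names is not reported here. Alternatives chosen before the data were examined were DESeq2 1.42.0, library totals or upper-quartile factors, no filter, at least 50 reads in each of 2 libraries, the series as a batch block, each library left out in turn, each read start counted once, thinning to the smallest library, both strands, assignment by the first base, rRNA, tRNA and mitochondrial genes left out, windows of 200 and 1000 bases, and other hexamer thresholds and prior counts. For both strands, strand was ignored in assigning reads, and reads touching more than one gene of either strand were left out.

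The tests were tried on simulated counts with 200 genes changed. With the means and depths of the gene reads (5372 genes), edgeR recovered 3.03% of genes changed by a log2 fold of 1, 42.4% at 2 and 86.9% at 4, with 0 of 5179 unchanged genes called, and DESeq2 recovered 6.06%, 54.5% and 90.2% with 19 called. With read starts counted once (3776 genes), edgeR recovered 28.1%, 83.6% and 100%, with 5 of 3579 unchanged genes called. For windows (18384) the recovery at a log2 fold of 2 and 4 was 3.23% and 37.7%. A simulated list of 30 genes raised 4-fold had a fry p of 0.00365 and a camera p of 0.00915 with an estimated correlation. The simulated counts held no difference between the series and no limit on read starts, and the fit with the block was not tried. These rates may therefore not hold for the data.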

Results

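RNA bound to the protein Mmi1 was profiled in wild-type fission yeast (Schizosaccharomyces pombe, strain SPV8) growing mitotically in rich medium. Mmi1 is a YTH-domain RNA-binding protein. It recognises the RNA hexamer UNAAAC (N, any base) and directs meiotic transcripts to nuclear degradation while cells divide by mitosis. RNA was recovered with an anti-Mmi1 antibody (Mmi1 IP 1 and Mmi1 IP 2) or with an irrelevant antibody (control IP 1 and control IP 2), and the only comparison that the design implies asks which RNAs the anti-Mmi1 antibody enriched over this background. The libraries held 178839998 reads in control IP 1, 80298136 in Mmi1 IP 1, 13223175 in control IP 2 and 45972112 in Mmi1 IP 2. Control IP 1 and Mmi1 IP 1 have reads of 47 bases and carry the letters BC in the deposited file names. Control IP 2 and Mmi1 IP 2 have reads of up to 53 bases and carry the letters LT there, though not in the sample titles. These 2 series are treated below as library batches, and ratios within each series stand beside the pooled values.

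Ribosomal RNA filled most of every library. It took 90.6% of the mapped reads in control IP 1, 87.1% in Mmi1 IP 1, 82.2% in control IP 2 and 84.4% in Mmi1 IP 2. This left 11501226, 6598428, 1999800 and 6216609 other reads, in the same order. As a share of all reads assigned to genes, rRNA was 86.7% ± 5.82 in the control IPs and 86.1% ± 1.89 in the Mmi1 IPs (SD, n = 2 each; exact permutation p = 1, two-sided). The difference, Mmi1 IP minus control IP, was -0.598 percentage points, and it was 3.52 without control IP 1, -4.71 without control IP 2, -1.93 without Mmi1 IP 1 and 0.739 without Mmi1 IP 2. Among assigned reads that were not rRNA, mRNA took 98.3% ± 0.256 in the control IPs and 97.6% ± 0.410 in the Mmi1 IPs. Long non-coding RNAs took 1.38% ± 0.128 of these reads in the control IPs and 1.90% ± 0.0389 in the Mmi1 IPs. In the BC series their share was 1.47% in the control and 1.93% in the Mmi1 IP, and in the LT series 1.29% and 1.87%. Both Mmi1 IPs were above both control IPs, with an exact permutation p of 0.333, which is the smallest that 2 against 2 libraries can give. Transfer RNA was 0.430% of these reads in Mmi1 IP 1 and 0.0565% in Mmi1 IP 2, against 0.147% and 0.0825% in the corresponding controls, so the libraries of one antibody differed more than the antibodies did.

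A non-coding RNA upstream of a mating gene and the mRNAs of 2 genes named for their induction in meiosis headed the RNAs recovered with anti-Mmi1. The long non-coding RNA nam1 (SPNCRNA.1459), transcribed upstream of the mating kinase gene byr2, rose from 1.92 ± 1.08 normalised reads per 1000000 gene reads (CPM) in the control IPs to 44.2 ± 19.2 in the Mmi1 IPs (SD, n = 2 each), a log2 fold change of 4.43 (SE 0.48, adjusted p = 0.00323). The mRNA of mug8 (SPAC32A11.01; mug, meiotically upregulated gene) rose from 1.72 ± 0.479 to 23.7 ± 7.23 CPM, a log2 fold change of 3.74 (SE 0.46, adjusted p = 0.0065). The mRNA of mug45 (SPBP8B7.04) rose from 0.542 ± 0.548 to 14.6 ± 3.34 CPM, a log2 fold change of 4.53 (SE 0.70, adjusted p = 0.0454). The increase was present in both series. It was 11.4-fold in BC and 50.1-fold in LT for nam1, 8.99-fold and 20.8-fold for mug8, and 13.2-fold in BC for mug45, which in LT had 2 reads in the control and 798 in the Mmi1 IP. The LT folds of nam1 and mug8 also rest on few control reads. In control IP 2 nam1 had 15 reads at 7 read starts and mug8 had 18 at 4. In assembly ASM294v3 nam1 lies on chromosome II from 1742555 to 1744043 on the minus strand, has 1 exon and carries 9 UNAAAC hexamers. The gene mug8 lies on chromosome I from 2445242 to 2447714 on the plus strand, with 3 exons and 14 UNAAAC hexamers in the spliced transcript, and mug45 on chromosome II from 3638417 to 3640971 on the plus strand, with 2 exons and 18 hexamers.

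Of 5574 genes tested, these 3 passed an adjusted p of 0.05 upwards and 0 downwards in edgeR's quasi-likelihood test, and 158 had an unadjusted p under 0.05. The count depended strongly on the fit. DESeq2 called 29 genes higher and 2 lower, edgeR with the series as a batch block called 27 higher and 9 lower, and edgeR with each read start counted once called 18 higher and 0 lower. The count was 0 with both strands. There, reads touching more than 1 gene of either strand were left out, and 3879 genes were tested. The RNA nam1 passed in 18 of the 19 settings. The fit with the series as a block leaves 1 residual degree of freedom. Its p-values, here and below, therefore rest mostly on variance shared across genes.

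The next 12 genes by p, which missed the threshold over all genes, were mostly genes of meiosis, and with the series as a block all 12 passed it, spo5 with the highest adjusted p (0.00137). They included the meiotic cyclin gene crs1 (log2 fold change 4.78, SE 0.81, adjusted p = 0.0698), mug4 (4.39, SE 0.76, adjusted p = 0.0698), the dynactin gene ssm4 (5.29, SE 0.96, adjusted p = 0.0894) and mei4, which encodes the forkhead transcription factor of middle meiosis (3.34, SE 0.63, adjusted p = 0.0942). The dynein anchor gene num1, also called mcp5, had 4.96 (SE 0.96), the meiotic cohesin gene rec8 had 4.58 (SE 0.96), the recombination gene mcp7 had 4.50 (SE 1.0) and spo5, encoding a meiotic RNA-binding protein, had 3.93 (SE 0.87). The gene mug9 had 1 read in the 2 control IPs together and 790 in the Mmi1 IPs, a ratio of 810 after normalisation with a counting interval of 145 to 32020. The 790 reads began at 13 positions in Mmi1 IP 1 and 24 in Mmi1 IP 2, and the interval takes them as independent. Levels in single libraries differed. For rec8 the CPM was 2.22 in Mmi1 IP 1 and 20.8 in Mmi1 IP 2, against 0.397 and 0.616 in the controls, and ssm4 and mcp7 had no read in control IP 2. The only ribosomal protein gene in this group was rps2202 (SPAC5D6.01), at 34.3 ± 2.62 CPM in the control IPs and 102 ± 35.3 in the Mmi1 IPs (log2 fold change 1.57, SE 0.31, adjusted p = 0.0994), with 4.66% of its reads from sequence that occurs elsewhere in the genome. Of the 15 genes with the smallest p and a positive fold, 14 carried at least 3 UNAAAC hexamers, and rps2202, with 1, was the exception. Among all 5574 genes tested, 3171 carried at least 3.

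**Figure D1:**
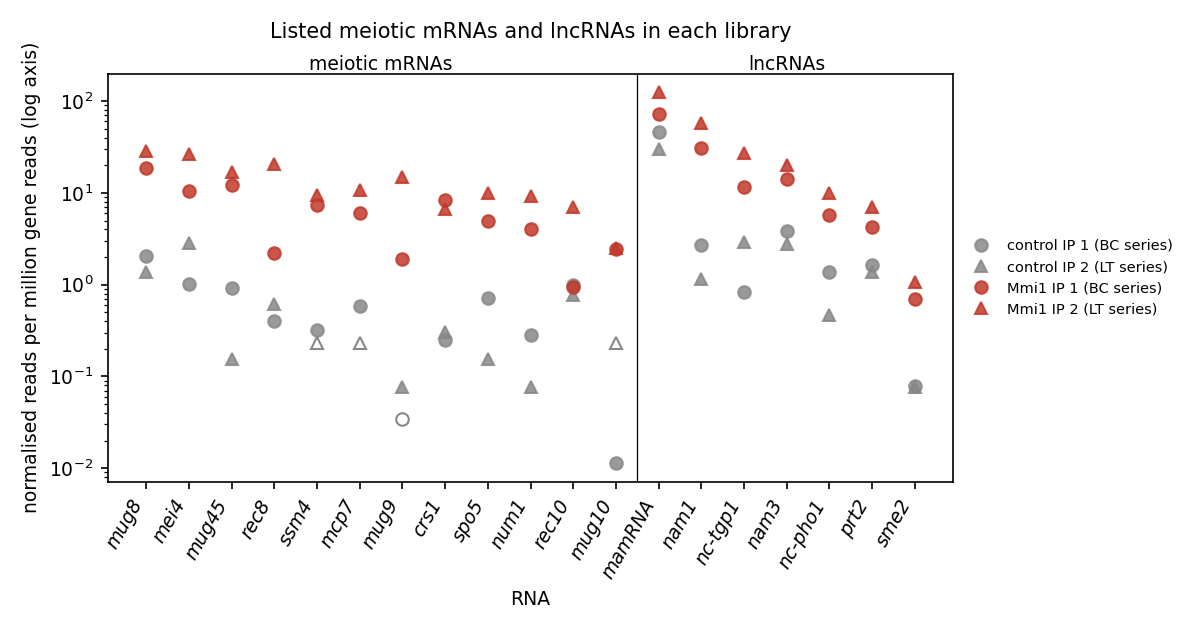
Normalised reads per 1000000 gene reads (log axis) of each tested meiotic mRNA and long non-coding RNA of the lists of known Mmi1 targets, 1 point per library (grey, control IP; red, Mmi1 IP; circles, BC series; triangles, LT series; open symbols, no read, drawn at the level of 3 reads). For 18 of the 19 RNAs both Mmi1 IPs lie above both control IPs, and rec10 is the exception.

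Meiotic mRNAs known to depend on Mmi1 formed the list with the largest median. All 12 tested members had a positive log2 fold change, with a median of 4.55 (3.49 in the BC series and 5.84 in the LT series). Of these, 2 rose at the threshold over all genes and 11 when adjusted over the list alone. With the series as a block 10 passed over all genes, and with each read start counted once 10 of the 10 that could be tested. The member that missed the threshold over the list alone was rec10, a gene of the meiotic chromosome axis. Its ratio was 0.949 in BC and 9.07 in LT. With the block, rec10 (adjusted p = 0.981) and mug10 (adjusted p = 0.154) missed the threshold. The gene mug10 had 1 read in the control IPs together and 243 in the Mmi1 IPs, a ratio of 249 with a counting interval of 44.3 to 9877. The 243 reads began at 12 positions in Mmi1 IP 1 and 8 in Mmi1 IP 2, and the interval takes them as independent. No read of mde3 was found in any library, where the level of 3 reads is 0.034 CPM in control IP 1, 0.0579 in Mmi1 IP 1, 0.231 in control IP 2 and 0.0639 in Mmi1 IP 2. As a set the list missed the threshold in limma's fry, with an adjusted p of 0.167 over the 15 lists, while fry's test for change in either direction gave an adjusted p of 0.0362. In limma's camera with the preset correlation of 0.01 the adjusted p was 9.13e-18, and with an estimated correlation the adjusted p was 0.437.

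Long non-coding RNAs known to be bound by Mmi1 formed a further list. Whether members became known through immunoprecipitation of Mmi1, in these or other libraries, was not checked. The list may therefore not be independent of the comparison made here. All 7 tested members had a positive log2 fold change, with a median of 3.0 (2.02 in BC and 3.21 in LT). Only nam1 rose at the threshold over all genes, and 6 did when adjusted over the list alone. With the series as a block 5 passed over all genes, namely nam1, nc-tgp1 (adjusted p = 1.16e-11), mamRNA (adjusted p = 4.84e-06), nam3 (adjusted p = 2.17e-05) and nc-pho1 (adjusted p = 0.0164). The RNA nc-tgp1, upstream of the transporter gene tgp1, had 1.88 ± 1.48 CPM in the control IPs and 19.5 ± 11.1 in the Mmi1 IPs (log2 fold change 3.48, adjusted p = 0.0942), and nam3 had 3.32 ± 0.773 and 17.2 ± 4.32 (2.35, adjusted p = 0.0994). The RNA nc-pho1, upstream of the acid phosphatase gene pho1, had a log2 fold change of 3.0, prt2, upstream of the phosphate transporter gene pho84, had 1.90, and mamRNA had 1.38. The meiotic RNA sme2, on which Mmi1 is sequestered in meiosis, was scarce here, with 7 and 1 reads in the control IPs and 36 and 50 in the Mmi1 IPs (log2 fold change 3.45, SE 2.15). No read of nam5 or nam6 was found in any library. The list's fry p was 0.0233 (adjusted p = 0.175), its camera adjusted p was 1.88e-10 and its adjusted p with an estimated correlation was 0.437.

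The protein-coding genes that these non-coding RNAs control were tested as a list of their own. Their log2 fold changes were 0.79 for byr2, 0.23 for tgp1, -0.25 for pho84 and -0.83 for pho1, with a list median of -0.01, and none of the 4 passed at either adjustment. Limma's fry gave the list an adjusted p of 0.757. Reads in the parts where nc-pho1 overlaps pho1 and prt2 overlaps pho84 were left out, since both RNAs of each pair lie on the same strand. On chromosome II pho1 spans 4447506 to 4449053 and nc-pho1 ends at 4448918. Likewise, pho84 spans 4444101 to 4446200 and prt2 ends at 4445970. The values of pho1 and pho84 therefore come from their 3' ends only. The SEs were 0.76 for byr2, 1.37 for tgp1, 1.28 for pho84 and 2.19 for pho1, so a change in these mRNAs is not excluded. Within 1 locus, the whole of nam1 was 11.4-fold higher in BC and 50.1-fold in LT, and the whole of byr2 2.42-fold and 1.39-fold. This difference was not tested. Inside nam1, the 500-base window of chromosome II from 1743001 to 1743500 held 1162 and 2499 reads in the Mmi1 IPs. The controls held 220 and 15 there, as raw reads that do not allow for library size.

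**Figure D2:**
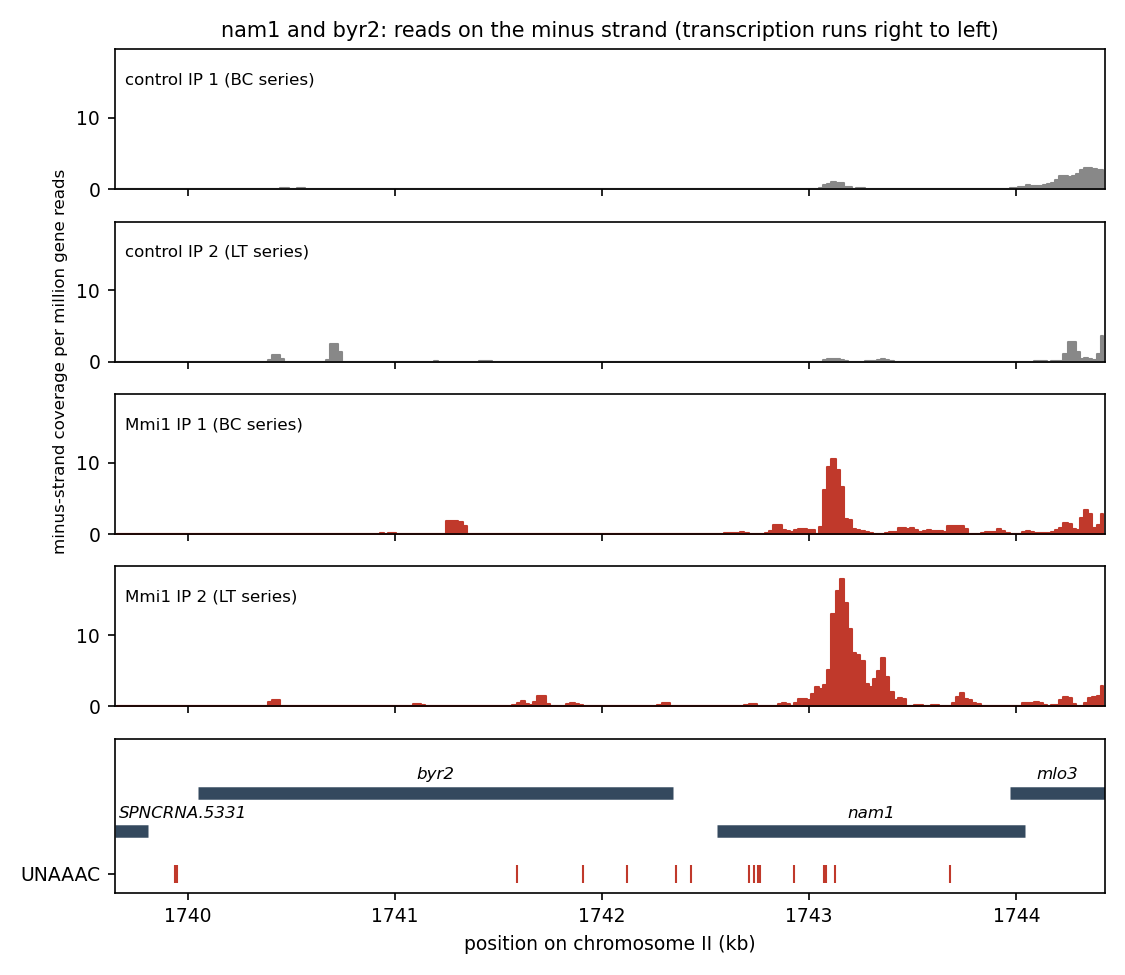
Coverage of minus-strand reads per 1000000 gene reads, in bins of 20 bases along chromosome II (kb), in each of the 4 libraries over nam1 and byr2, with the annotated minus-strand genes (bars) and minus-strand UNAAAC hexamers (red ticks) below. The Mmi1 IPs peak inside nam1, where the controls stay low, and byr2 has little coverage in all 4.

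Of the 793 non-coding genes tested, nam1 alone rose and 0 fell (edgeR), and 53 had an unadjusted p under 0.05. The 5 with the smallest p were nam1, nc-tgp1, nam3, mamRNA and SPNCRNA.1626, and the last was the only one outside the list of known bound RNAs. SPNCRNA.1626, on chromosome II from 3626024 to 3631136 on the minus strand, had 9.60 ± 5.30 CPM in the control IPs and 31.6 ± 10.9 in the Mmi1 IPs (log2 fold change 1.70, SE 0.43, adjusted p = 0.428, or 4.62e-06 with the series as a block and 0.289 with each read start counted once). It carries 10 UNAAAC hexamers over 5113 nucleotides. DESeq2 called 9 non-coding genes changed, the fit with the series as a block 14, and the count with each read start taken once 5. Without single libraries the count was 14 (control IP 1), 11 (Mmi1 IP 1), 8 (control IP 2) and 10 (Mmi1 IP 2).

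Other meiotic lists split into members that were recovered with anti-Mmi1 and members that were not. Of 11 tested genes for meiotic recombination and chromosome structure, 9 had a positive fold, with a median log2 fold change of 4.06, or 3.84 with the member without control reads at its bound. None of them passed over all genes and 7 did when adjusted over the list alone, 3 of which (rec8, mcp7 and num1) also stand in the list of known targets. With the series as a block 5 passed over all genes. Of these genes rec27 had 1 read in the control IPs together and 194 in the Mmi1 IPs, and all 64 of its reads in Mmi1 IP 1 began at 1 position. The camera adjusted p of this list was 4.63e-09 (adjusted p = 0.437 with an estimated correlation). The 79 tested mug and meu genes had a median of 0.06 and a mean of 0.76, 6 of them passing when adjusted over the list alone, of which mug8, mug9, mug10 and mug45 also stand in the list of known targets. Their camera adjusted p was 0.00262 (adjusted p = 0.437 with an estimated correlation). The 10 genes of spore formation had a median of -0.08, and spo5 was the 1 member past the threshold adjusted over the list alone, while isp3 had -1.85, spo2 -1.41 and spo15 0.27. The 17 regulators of mating had a median of 0.69, and rep1, encoding a transcription factor subunit of premeiotic S phase, was the 1 member past that threshold, with a log2 fold change of 4.56 (SE 1.05, adjusted p = 0.300 over all genes, or 9.89e-06 with the series as a block and 0.0647 with each read start counted once). Control IP 2 held no read of rep1, so its fold rests on control IP 1, with 48 reads. In the same list ras1 had 1.28, the meiotic inhibitor kinase gene pat1 had 1.12 and the formin gene fus1 had 0.94.

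The mRNA of mmi1 itself had 23.9 ± 1.43 CPM in the control IPs and 57.5 ± 16.9 in the Mmi1 IPs (log2 fold change 1.27, SE 0.31, adjusted p = 0.376). It was the 1 of 16 genes of Mmi1, its partner Erh1, the MTREC complex and the nuclear exosome that passed when adjusted over the list alone, and it passed over all genes with the series as a block (adjusted p = 0.000239) but not with each read start counted once (adjusted p = 0.547). The list lay near 0 (median 0.02, mean -0.06), with erh1 at -1.86 (SE 1.25), cbc1 at 0.50 and the poly(A) polymerase gene pla1 at -0.40. None of the 8 genes of the CCR4-NOT deadenylase passed (median -0.03; rcd1 -0.84, ccr4 -0.28, mot2 -0.21, not3 0.18), nor did the 18 of heterochromatin and RNA interference (median 0.20; tas3 -1.60, hrr1 1.16, cid12 0.96). Neither did the 3 tested Tf2 retrotransposons (Tf2-2 0.22, Tf2-3 0.13, Tf2-7 2.45), whose reads all come from repeated sequence and cannot be assigned to one copy.

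Abundant mRNAs of growing cells served as a background. The 141 ribosomal protein mRNAs had a median log2 fold change of -0.20 (-0.14 in BC and -0.29 in LT), with a camera adjusted p of 0.00262 downwards and an adjusted p of 0.711 with an estimated correlation. The largest decreases by p were rps802 (-0.64), rps403 (-0.58) and rps801 (-0.57), all with an adjusted p of 0.999. With library totals only the list's median was 0.01, where the median of all genes was 0.25. With each read start counted once the list's median turned to 0.40 (camera adjusted p = 2.73e-15 with the preset correlation), so its direction depends on the counting. Transcript length limits the read starts of such abundant mRNAs. Over its 689 nucleotides rps801 had 567 starts in control IP 1 and 317 in Mmi1 IP 1. The turn is therefore not evidence that anti-Mmi1 recovered these mRNAs. The 15 mRNAs of glycolysis and fermentation had a median of -0.32, with pgk1 at -0.53, gpm1 at -0.52, pgi1 at -0.40 and tpi1 at -0.38 (camera adjusted p = 0.0578). Their median also turned with each read start counted once, to 0.18 (camera adjusted p = 0.0126 with the preset correlation), where the same limit on read starts applies. The 10 histone mRNAs (median -0.02; hht3 0.48, pht1 -0.48, hta2 -0.26, hht2 -0.19) and the 17 of the stress response (median -0.19; isp6 -0.59, hsp90 -0.36, ntp1 -0.31, ctt1 -0.31) had no member past the threshold. By fry's test for a shift to one side, 0 of the 15 lists passed an adjusted p of 0.05 and 2 had an unadjusted p under 0.05, those of the known mRNAs and the known non-coding RNAs. With the series as a block, no list passed with an estimated correlation in camera (adjusted p = 0.792 for the known mRNAs).

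**Figure D3:**
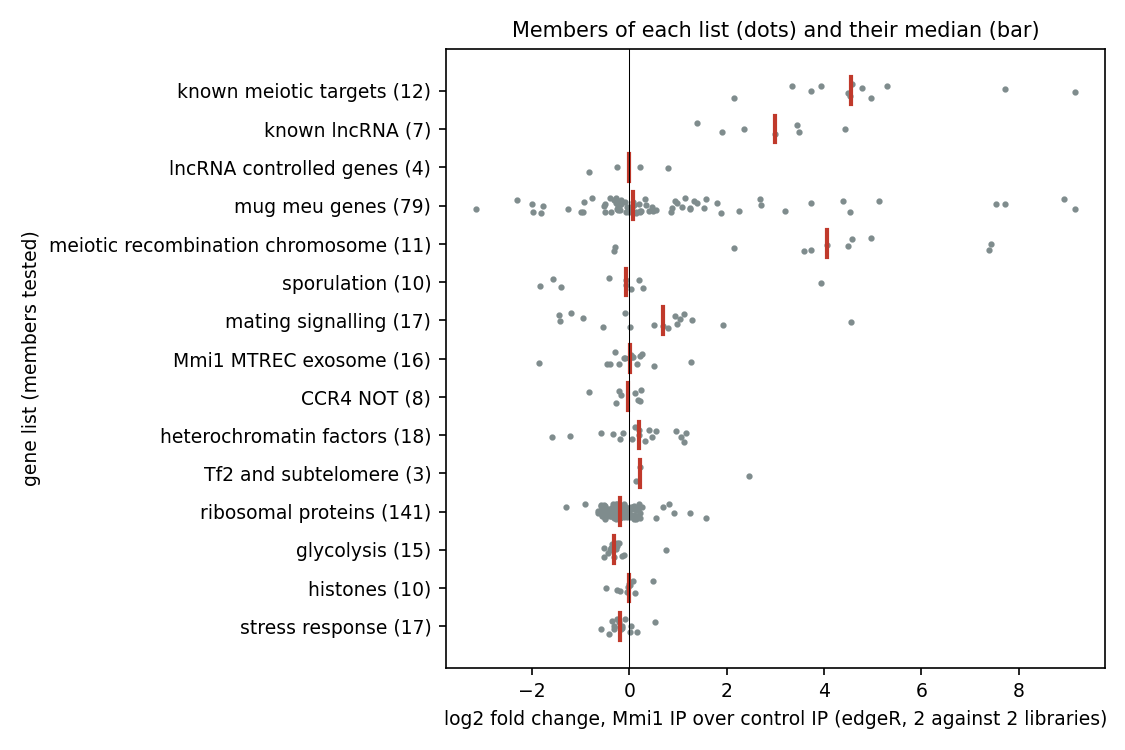
log2 fold change (Mmi1 IP over control IP) of each tested member (dots) and the median (red bar) of the 15 gene lists, with the number of members tested. The medians are 4.55 for known meiotic targets, 4.06 for meiotic recombination genes and 3.0 for known long non-coding RNAs, and the other 12 lie between -0.32 and 0.69.

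The hexamer UUAAAC, a form of UNAAAC, was the sequence most strongly tied to recovery in the Mmi1 IP. In a regression of the log2 fold change on the number of each hexamer per transcript, with transcript length as a covariate, UUAAAC had a t of 9.96 and ranked 1 among all hexamers, ahead of AUUAAA with 6.49. The other forms ranked 11 (UAAAAC, t 5.09), 14 (UGAAAC, t 4.76) and 23 (UCAAAC, t 4.19). Genes are not independent replicates, so t is used here only to rank hexamers. UUAAAC ranked 1 in every setting tried except without control IP 1, where it ranked 9 (t 8.40). The difference between genes was small. The 3171 genes with at least 3 UNAAAC hexamers had a median log2 fold change of 0.03 and the 2403 others of -0.05, a difference of 0.08 that missed the threshold (camera p = 0.111, or p = 0.226 with an estimated correlation; fry p = 0.389). Genes with 10 or more hexamers (n = 230) had a median of 0.13 (0.02 in BC and 0.17 in LT) and genes with 0 (n = 583) of -0.12 (-0.12 in BC and -0.16 in LT). The Spearman rho of the hexamer number with the log2 fold change was 0.0832 across genes. With transcript length removed rho was 0.0989. The difference of 0.08, which is not corrected for length, turned to -0.05 with each read start counted once and to -0.09 without control IP 1, where rho was -0.0933 and -0.0196, and with length removed 0.115 and 0.129.

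**Figure D4:**
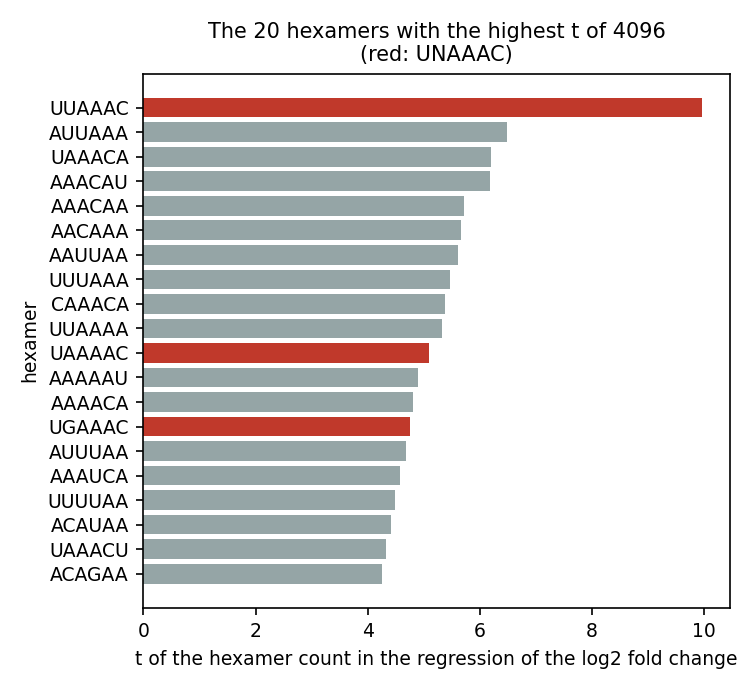
t of the number of each hexamer in the regression of the log2 fold change on hexamer number and transcript length across 5574 genes, for the 20 hexamers with the highest t (red, the UNAAAC forms). UUAAAC stands first at 9.96, and UAAAAC and UGAAAC are also among the 20.

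The distribution of reads around UNAAAC was taken within the 3 RNAs that rose. The density within 100 nucleotides of a hexamer, relative to the whole gene, was 1.46 in Mmi1 IP 1 and 1.21 in Mmi1 IP 2 as a mean over genes, against 1.26 in control IP 1 and 0.689 in control IP 2 (2 genes with enough reads). Around the reverse complement GUUUNA it was 1.33 and 1.04 in the Mmi1 IPs and 0.699 and 0.256 in the controls, so the excess over the control was not particular to UNAAAC. Over all listed meiotic mRNAs and non-coding RNAs it was 1.37 and 1.45 in the Mmi1 IPs (19 genes each) and 1.24 (16 genes) and 1.47 (8 genes) in the controls. With each read start counted once it was 1.36 and 1.28 in the Mmi1 IPs and 1.19 and, over 2 genes, 0.558 in the controls. These means rest on different genes and were not tested.

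Windows of 500 bases on each strand were tested to find RNA outside annotated genes. Of 20035 windows, 0 passed an adjusted p of 0.05 in edgeR and 498 had an unadjusted p under 0.05. DESeq2 called 42, edgeR with the series as a block 35, and edgeR with each read start counted once 31, all of these 31 higher in the Mmi1 IP. Without single libraries the count was 12 (control IP 1), 33 (Mmi1 IP 1), 15 (control IP 2) and 46 (Mmi1 IP 2). Of the 5 windows outside genes with the smallest p, the first lay on chromosome III from 1452001 to 1452500 on the plus strand, antisense to SPNCRNA.1197. It held 33 and 0 reads in the controls and 307 and 781 in the Mmi1 IPs (log2 fold change 5.56, SE 1.0, adjusted p = 0.473), and it passed with the series as a block (adjusted p = 1.45e-09) and with each read start counted once (adjusted p = 4.76e-15). The next 3 were on chromosome II from 520501 to 521000 (6.20), chromosome I from 1494001 to 1494500 (3.0) and chromosome III from 16001 to 16500 (3.97), all on the minus strand. The fifth, on chromosome I from 4786501 to 4787000 on the minus strand, had a log2 fold change of -3.44. None of these 4 passed with the series as a block.

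Across the 5574 genes the log2 ratio of Mmi1 IP to control IP in the BC series had a Pearson r of 0.129 with that in the LT series (95% interval 0.103 to 0.155; Spearman rho 0.0903), and 52.7% of genes had the same sign. With each read start counted once r was 0.00638 over 3984 genes, rho was -0.117 and 45.3% had the same sign. Over the 19 listed meiotic mRNAs and long non-coding RNAs r was 0.639 and 94.7% had the same sign, and over the 5555 other genes r was 0.105 (Spearman rho 0.0822). The interval takes genes as independent, which they are not. The listed non-coding RNAs may have become known through immunoprecipitation of Mmi1, so their agreement may not be independent support. The correlation of log-CPM across genes was 0.883 between the controls and 0.844 between the Mmi1 IPs, and 0.890 between antibodies in the BC series and 0.838 in the LT series. For pairs sharing neither antibody nor series it was 0.890 (control IP 1 and Mmi1 IP 2) and 0.802 (Mmi1 IP 1 and control IP 2). These values therefore do not weigh antibody against series.

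**Figure D5:**
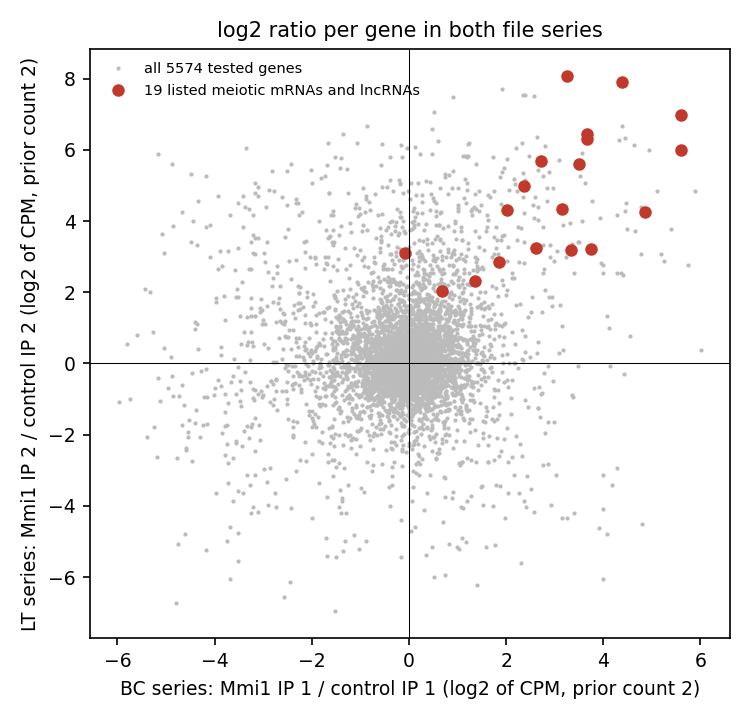
log2 ratio of Mmi1 IP to control IP per gene in the BC series (horizontal) and the LT series (vertical), 1 point per tested gene (grey, 5574 genes; red, 19 listed meiotic mRNAs and long non-coding RNAs). The listed RNAs fill the upper right, where both ratios are positive, apart from rec10 at -0.08 in BC, while the cloud of all genes has r = 0.129.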

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

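The test of UNAAAC within introns was chosen only after the result was seen. Introns stood apart when reads across exon-intron borders were set against reads that join exons, which the comparisons of genes do not use. Of the reads that cross an exon-intron border or join 2 exons, 10.9% were unspliced in Mmi1 IP 1 (95% Wilson interval 10.7 to 11.1) and 15.9% in Mmi1 IP 2 (15.6 to 16.1), against 6.49% in control IP 1 (6.37 to 6.61) and 8.01% in control IP 2 (7.70 to 8.33). These intervals take copies as independent reads and are too narrow to that extent. In Mmi1 IP 1, for example, the 10655 unspliced reads were 723 distinct ones. The ratio of Mmi1 IP to control was 1.69 in the BC series and 1.98 in the LT series, and 1.18 and 1.96 over distinct reads. The intron of rps2202 (chromosome I, 1512199 to 1512345, minus strand) had 231 and 667 unspliced reads in the Mmi1 IPs against 46 and 0 in the controls, while its spliced reads were 88 and 63 against 123 and 38. Not every intron behaved so. The intron of the ribosomal protein gene rps13 at 2746240 to 2746302 of the same chromosome, chosen after its values were seen, had 512 and 409 unspliced reads beside 981 and 692 spliced in the Mmi1 IPs, and 743 and 195 beside 1481 and 197 in the controls.

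Genomic DNA would add antisense reads over the same borders, and their rise was at most 11.6% of that of the sense unspliced reads, which argues against it as the whole source. Without the 5 introns with the most unspliced reads the smaller ratio was 1.69, close to that of all introns, which argues against a few introns as the whole source. Over distinct reads the ratio without them was 1.14 in BC and 1.99 in LT, so in BC the difference was then small. Read length limits the distinct reads per junction. In control IP 1, the deepest library, introns of rpl35A02 and rps1901 each had 36 distinct spliced reads, from 1363 and 5450 reads. The unspliced share of control IP 1 was 10.7% over distinct reads and 6.49% over all reads. How far copies or this limit lowered the ratio in BC was not tested. A candidate explanation is that Mmi1 binds UNAAAC within introns of unspliced RNA. Over distinct reads without rps2202, the rise was larger by 0.44 on the log2 scale for the 598 introns with the hexamer (permutation p = 0.0059 over 10000 random sets), but over all reads it was 0.18 (permutation p = 0.513), so this stays open. The distinct-read ratio of these introns was 1.31 in BC and 2.83 in LT, against 1.14 and 1.78 without the hexamer. For GUUUNA the rise was larger by 0.080 over distinct reads (permutation p = 0.528) and 0.33 over all reads (permutation p = 0.153). The random sets vary introns within the same libraries, so p does not measure the spread between immunoprecipitates. Recovery of nuclear RNA in general, and differences between the 2 libraries of a group, may also contribute and were not tested.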

How the results depend on the processing

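Of 1087 alternatives over the named genes, 850 kept their direction and their side of the threshold, 177 passed it newly, 4 no longer passed and 56 turned in sign. The number of genes past the threshold, 3 at first, was 31 with DESeq2, 27 with library totals only, 27 without a filter, 7 with at least 50 reads in each of 2 libraries, 36 with the series as a block, 18 with each read start counted once, 6 after thinning, 0 on both strands, 13 without rRNA, tRNA and mitochondrial genes, and 19 to 41 without single libraries. It was 3 with upper-quartile factors and 2 by the first base. The non-coding count, 1 at first, was in the same order 9, 7, 11, 1, 14, 5, 2, 0, 3 and 8 to 14, and 1 in the last 2. Windows past the threshold, 0 at first, were 42 with DESeq2, 35 with the block, 31 with read starts once, 12 to 46 without single libraries, and 0 at 200 and 1000 bases. Chosen after the data were seen, read starts once with the block gave 23 genes, 8 non-coding and 38 windows; without repeated sequence 12 genes and 3 non-coding; and read starts once and thinned 13 genes and 5 non-coding. By fry's test for a shift to one side no gene list passed in the 14 alternatives run for lists. Its test for change in either direction, past the threshold for the known meiotic mRNAs (adjusted p = 0.0362), also passed for them with DESeq2 (0.0373), upper-quartile factors (0.0383), at least 50 reads (0.0335, also the mug and meu genes) and without repeated sequence (0.034), and in none of the other 10. A fit without 1 library assumes that the lone sample varies like the other group. The cause was not tested for any of these changes. The block on the series is also a block on the replicate number. It leaves 1 residual degree of freedom, so its calls rest mostly on variance shared across genes.

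The difference by UNAAAC number was 0.134 at 1 or more hexamers, past the threshold in camera with the preset correlation (p = 0.0352) but not with an estimated correlation (p = 0.141) or in fry (p = 0.628). It was -0.0539 with read starts once, -0.0702 with read starts once and the block, -0.0695 with read starts once and thinned, and -0.0925 to 0.166 without single libraries. The rho of hexamer number, 0.0832 at first, was -0.0933 with read starts once, -0.118 with the block as well, -0.0951 when thinned and -0.0196 without control IP 1, and with transcript length removed it was 0.115 with read starts once and 0.129 without control IP 1. The agreement of the series had an r of 0.00638 with read starts once. Read starts are limited by transcript length in abundant mRNAs (pgk1 had 1512 starts over 1641 nucleotides in control IP 1), which bears on signs that turn by counting starts once in such mRNAs. Whether it bears on the agreement of the series was not tested. The following log2 fold changes turned in sign, and the cause was not tested. On both strands, where reads touching more than 1 gene of either strand were left out, byr2 had -1.74, tgp1 -2.56, ccr4 0.22, mot2 0.90 and hta2 0.18. With library totals pho84 had 0.082, and with the series as a block tgp1 had -0.15 and Tf2-3 -0.22. With read starts once pho84 had 0.11, rcd1 0.024, rps802 0.22, rps801 0.28, rps403 0.32, pgk1 0.20, gpm1 0.18, pgi1 0.13, tpi1 0.29, hta2 0.15, hht2 0.18, hsp90 0.19 and ctt1 0.029. With the block as well, pho84 had 0.33, rps802 0.43, rps801 0.61, rps403 0.46, pgk1 0.73, gpm1 0.64, pgi1 0.33, tpi1 0.62, hta2 0.20, hht2 0.23, hsp90 0.65 and ctt1 0.013. Read starts once and thinned gave ccr4 0.083, rps802 0.023, rps801 0.32, rps403 0.27, pgk1 0.20, gpm1 0.14, pgi1 0.14, tpi1 0.25, hta2 0.23, hht2 0.057 and hsp90 0.17. Without single libraries the range was -2.18 to 0.88 for pho84, -1.22 to 0.97 for tgp1, -0.15 to 1.98 for ras1, -0.43 to 0.036 for mot2, -1.83 to 1.3 for Tf2-3, -0.99 to 0.023 for pht1, -0.53 to 0.24 for hht2, -1.19 to 0.49 for isp6, -0.75 to 0.16 for hsp90 and -0.60 to 0.051 for ctt1.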

Other observations

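All the windows and genes of this paragraph and the next except mug4, the first window outside genes and the known targets were chosen after their values were seen, and so were the tests of PCR copies, repeated sequence and listed targets alone. With each read start counted once, 31 windows of 500 bases were higher in the Mmi1 IP (edgeR), and 16 of them lay in known targets. Several lay at or past the annotated 3' end of genes that did not change as a whole. Downstream of the ribosomal protein gene rpl3202 (chromosome I, 3415001 to 3415500, minus strand, 407 of 500 bases outside genes, 8 UNAAAC) the window held 406 and 571 reads in the Mmi1 IPs against 17 and 0 in the controls (log2 fold change 4.87 with read starts counted once, adjusted p = 9.4e-15), while rpl3202 itself had a log2 fold change of 0.05 (SE 0.30). Downstream of SPCC61.05 (chromosome III, 1451501 to 1452000, plus strand, 389 bases outside genes) the window held 347 and 739 reads against 14 and 1 (4.83, adjusted p = 8.09e-10), while SPCC61.05 had -0.38 (SE 0.52). The next window, the first of the windows outside genes, continued this stretch. A window at the end of rps1102 (chromosome I, 4675001 to 4675500, plus strand) had 2.06 (adjusted p = 2.75e-06).

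Introns and single genes outside meiosis appeared as well. A window of the RNA helicase gene dbp2 (chromosome II, 3663501 to 3664000, minus strand), of which 405 bases are intron, held 1172 and 1439 reads in the Mmi1 IPs against 275 and 115 in the controls (log2 fold change 2.54 with read starts counted once, adjusted p = 7.39e-09). A window of SPNCRNA.872 (chromosome I, 3002001 to 3002500, minus strand) had 3.83 (adjusted p = 7.34e-10), and 1 of mmi1 (chromosome III, 338001 to 338500, minus strand) had 1.79 (adjusted p = 0.00731). Of the 18 genes higher with each read start counted once, 15 were known targets and the other 3 were mug4, stb3 and rec25. The gene stb3 had a log2 fold change of 2.05 and an adjusted p of 0.412 over all reads, and 0.00802 with read starts counted once. With the series as a block the transfer RNA gene SPCTRNAGLY.10 was also called higher, at 300.3 CPM in Mmi1 IP 1 and 13.7 in Mmi1 IP 2 against 14.0 and 16.9 in the controls. This call rests on Mmi1 IP 1 alone, since Mmi1 IP 2 was below its control.

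The 19 listed meiotic mRNAs and non-coding RNAs all had a positive log2 fold change over the 4 libraries, though rec10 was not higher in BC (ratio 0.949). PCR copies of a few fragments would leave little difference once each read start is counted once. The smaller of the medians in the 2 series was then 2.85 (16 members), which argues against such copies for these 16. The members rec10, mug10 and sme2 had too few read starts to be tested, so PCR copies stay open for them. Reads from repeated sequence made up 0% of the reads of each member, which argues against them. Binding by Mmi1 is a candidate explanation that the antibody groups name, and since it was tested on the same libraries it stays a hypothesis.

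The hexamer UUAAAC ranked first among hexamers. With GC content also in the regression, its t exceeded that of the next of the 60 hexamers made of the same bases by 5.63, which argues against the A and U content of transcripts as the whole source. Without the listed targets its t was 7.47 and it still ranked 1, so these RNAs alone do not account for it. Weak binding of Mmi1 to many RNAs with UUAAAC may contribute, but without control IP 1 the hexamer ranked 9.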
